A study of Mus musculus with 10 samples.

How the data were processed

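RNA sequencing of mouse EpiSC, EpiLC, ESC and MEF was analysed from 2 deposited tables, 1 of counts and 1 of FPKM, each with 10 libraries and 54532 genes. The deposited counts are whole numbers per gene, made by the authors with featureCounts 1.5.0-p3 after alignment to mm10 with HISAT2 2.0.5, per the submitters' processing notes. The deposited FPKM were computed by the authors from those counts: each library's FPKM equalled its counts divided by gene length and by 1 constant per library, with a largest relative deviation of 1.7e-08 over counts above 20. These constants lay within 1% of those given by DESeq2 size factors, so the deposited FPKM are scaled between libraries by a normalization of that kind and not by total counts alone. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart; Wrap53 lies beside Trp53 on the opposite strand. Of the gene IDs, 54409 (99.8%) were found in GENCODE vM21, and 98.3% of these had identical coordinates there. Gene symbols were taken from the tables, and 105 symbols were shared by more than 1 gene ID.

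Groups were taken from the labels: haploid p53-KO EpiSC (n = 2), diploid wild-type EpiSC (n = 2), diploid p53-KO EpiSC (n = 1), haploid p53-KO EpiLC (n = 1), haploid wild-type EpiLC (n = 1), haploid ESC (n = 1), diploid ESC (n = 1) and MEF (n = 1). The design text speaks of triplicates, whereas 10 libraries were used here. Total counts ran from 15862113 to 18814003 per library. Levels of single libraries, and the group means of Hs3st3b1, are counts-per-million (CPM) normalised with TMM factors over all genes, with 95% Poisson intervals. Other means of a group beside a fold change are CPM with the TMM factors of that fit. A count of 0 was read as at most 3 counts per library, and where a whole side was at 0 the fold is given as a bound from that floor on the log2 scale. Shares of counts in single libraries carry exact (Clopper-Pearson) binomial 95% intervals. Pairs of libraries were compared by chi-square over genes, and the lowest chi-square per degree of freedom was 38.89.

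Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts, with the low-count filter of filterByExpr, TMM normalization and the quasi-likelihood F test with Benjamini-Hochberg adjustment at a threshold of 0.05. Cell types were compared in 1 fit of all 10 libraries with 1 mean per cell type. The 3 contrasts among EpiSC used the 5 EpiSC libraries with 1 mean per group. The p53 and ploidy contrasts over cell types used the 9 pluripotent libraries in an additive fit of cell type, p53 label and ploidy, and the interaction tests used the same 9 libraries with 1 mean per group. Groups of 1 library were assumed to vary like the others. Standard errors were the absolute log2 fold change divided by the square root of F. DESeq2 1.42.0 (Wald test, default filtering) and limma 3.58.1 (trend, on log2(FPKM + 1), genes of at least 1 FPKM in 1 or more libraries) were run beside it. The single EpiLC and ESC pairs were given as log2 ratios of TMM-normalised CPM with a prior count of 2, without a test; list medians were set against 10000 random lists of the same size matched on mean expression.

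The 22 gene lists with 427 entries, of which 426 matched a gene, were fixed before the data were examined, as were the groups, the contrasts, the tests and all alternatives except those said to be chosen after seeing the data. They were naive pluripotency, general pluripotency, post-implantation epiblast, primitive streak and mesendoderm, extraembryonic endoderm, trophoblast, neural, fibroblast, p53 targets, heparan sulfate enzymes, paternally and maternally expressed imprinted genes, germline, 2-cell-like, glycolysis, respiratory chain, mitotic cell cycle, FGF-ERK targets, Wnt targets, Nodal pathway, epithelial-mesenchymal transition and DNA methylation machinery. Lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of 239 such tests 91 passed with the preset and 1 with the estimated correlation. Members were counted over all genes tested and adjusted over the list alone.

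Named genes followed a rule. Trp53, Hs3st3b1, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were named in every sample. For each tested comparison the 8 genes up and 8 down with the largest log2 fold change were eligible among protein-coding genes past the threshold, with a mean of at least 5 CPM on the higher side and no overlap between the libraries of the sides; symbols of predicted genes and RIKEN clones were left out. From each list up to 4 members past the threshold with the largest absolute change were eligible, or else the 2 with the smallest p. In each single-library pair 5 genes per direction with at least 100 counts in either library were eligible. Of the eligible genes the report gives examples. The levels of Cdkn1a in every library, and its values in comparisons where the rule did not name it, were chosen after they were seen. Isg15, Ifit1 and Irf7, named in the closing section, were chosen after their values were seen.

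The balance of X-linked and autosomal genes was the median log2 level of X-linked genes minus that of autosomal genes, each gene taken relative to the mean of the 9 pluripotent libraries, with bootstrap intervals from 1000 draws. Chromosome medians used genes with a mean of at least 10 CPM. Balance of the labelled ploidies was compared with an exact permutation test.

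The alternatives tried were DESeq2 size factors in edgeR, no low-count filter, DESeq2, a 2-fold minimum, limma on FPKM with pseudocounts of 1 and 0.1 and without a filter, each library left out in turn, wild-type libraries only, covariates for p53 label and ploidy, other fits of the EpiSC groups, an estimated correlation for the lists, autosomal scaling for X-linked genes and a prior count of 0.5 for the single-library pairs. Alternatives without haEpi1 and haEpi5, without haEpi5 and the wild-type EpiLC library, and without genes of chromosome 12 or of the X and Y chromosomes were chosen after seeing the data. No library and no column of the tables was left out of the main analysis.

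The tests were tested on simulated data drawn from the real means and library sizes, with 2-fold, 4-fold and 8-fold changes. edgeR recovered 1.59%, 15.9% and 58.7% of these in the design of EpiSC against ESC (19809 genes tested), 0%, 17.2% and 42.2% in EpiLC against ESC (19823 genes), and 0%, 31.7% and 58.6% in EpiSC against EpiLC (19886 genes). It recovered 0%, 1.54% and 33.9% in EpiSC against MEF (19851 genes), 3.03%, 38.7% and 52.4% in haploid p53-KO against wild-type EpiSC (17489 genes), and 0%, 20.9% and 58.5% in diploid p53-KO against wild-type EpiSC (17500 genes). In the interaction test of p53 in EpiLC and diploid EpiSC it recovered 0% of each size (19266 genes). Calls among unchanged genes numbered 0 to 13 by edgeR and 17 to 96 by DESeq2 over the 11 designs. A simulated list of 20 genes shifted 2-fold had a camera p between 1.34e-16 and 0.0108, and 0 to 5 of 100 unchanged lists passed 0.05. With an estimated correlation that list had camera p between 0.000103 and 0.109, and 0 to 1 of the unchanged lists passed. The simulated genes were drawn independently of each other. These rates therefore do not show how the preset correlation performs on genes that move together.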

Results

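The transcriptomes of mouse pluripotent cells and fibroblasts were measured by RNA sequencing in 10 libraries of 8 groups and 4 cell types. Epiblast stem cells (EpiSC), which are derived from the post-implantation epiblast, gave 5 libraries. Their labels read haploid p53-KO (n = 2, lines haEpi1 and haEpi5), diploid wild type (n = 2, 1 male and 1 whose title ends in fema, read here as female) and diploid p53-KO (n = 1). Epiblast-like cells (EpiLC) gave 1 library labelled haploid p53-KO and 1 labelled haploid wild type; the design text of the series names WT-EpiLCs, with no ploidy. Embryonic stem cells (ESC) gave 1 library labelled haploid and 1 labelled wild-type diploid. Mouse embryonic fibroblasts (MEF) gave 1 library. The total count was 18814003 in haEpi1, 17316238 in haEpi5, 16885384 in the female EpiSC library, 17293965 in the male EpiSC library and 15905966 in the diploid p53-KO EpiSC library. It was 15862113 in the haploid p53-KO EpiLC library, 18156542 in the wild-type haploid EpiLC library, 17803421 in the haploid ESC library, 15899032 in the diploid ESC library and 18160992 in the MEF library. A count of 0 allowed a level of up to 0.150 (haploid ESC) to 0.194 (wild-type haploid EpiLC) TMM-normalised counts-per-million (CPM), from a floor of 3 counts per library. Intervals and floors cover counting error only. No pair of libraries agreed within sampling noise. The libraries of a replicated group differ in line (haEpi1 and haEpi5) or in sex (wild-type EpiSC) by their labels, so p-values measure the spread between these samples, which holds such differences beside technical ones. In the comparisons of cell types, libraries of different p53 label or ploidy share 1 mean. EpiSC mix both p53 labels and both ploidies, EpiLC both p53 labels and ESC both ploidies. The spread behind those p-values therefore also holds differences of p53 label and ploidy.

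Trp53, the gene of the tumour suppressor p53 and the target of the knockout named in the labels, lies on chromosome 11 at 69580359 to 69591873 (ENSMUSG00000059552, mm10). In the libraries labelled p53-KO its level was 50.5 CPM in haEpi1, 61.8 CPM in haEpi5, 2.17 CPM in diploid EpiSC (95% Poisson interval 1.51 to 3.02) and 32.9 CPM in haploid EpiLC. In the libraries labelled wild type it was 36.9 CPM in female EpiSC, 199 CPM in male EpiSC, 28.5 CPM in haploid ESC, 129 CPM in MEF, 375 CPM in diploid ESC and 356 CPM in haploid EpiLC. Thus haEpi1 and haEpi5 lay above the wild-type female EpiSC library and the wild-type haploid ESC library, and the Trp53 level did not separate the labelled genotypes. Each genotype below is therefore the one in the label. The part of the gene that was targeted is not given in the sources used here, so a transcript may remain from a disrupted gene. Cdkn1a, the cell cycle inhibitor that p53 activates, stood at 71.3 CPM in haEpi1 and 104 CPM in haEpi5. It stood at 4.34 CPM in the diploid p53-KO EpiSC library and 12 CPM in the haploid p53-KO EpiLC library. The wild-type libraries held 70.8 CPM (female EpiSC), 162 CPM (male EpiSC), 102 CPM (haploid ESC), 215 CPM (diploid ESC), 116 CPM (haploid EpiLC) and 158 CPM (MEF).

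Hs3st3b1, the heparan sulfate 3-O-sulfotransferase named in the title of the series, lies on chromosome 11 at 63885792 to 63922290 (ENSMUSG00000070407, mm10). Its level was 3.62 CPM in haEpi1, 1.15 CPM in haEpi5, 9.25 CPM in female EpiSC, 0.339 CPM in male EpiSC and 2.85 CPM in diploid p53-KO EpiSC. It was 2.27 CPM in p53-KO EpiLC, 0.774 CPM in wild-type EpiLC, 7.34 CPM in haploid ESC, 4.78 CPM in diploid ESC and 9.05 CPM in MEF. The mean was 3.44 ± 3.50 CPM in EpiSC (SD, n = 5), 1.52 ± 1.06 CPM in EpiLC (n = 2) and 6.06 ± 1.81 CPM in ESC (n = 2). The log2 fold change was -0.83 ± 0.92 (SE) between EpiSC and ESC (edgeR adjusted p = 0.579), -1.99 ± 1.19 between EpiLC and ESC (adjusted p = 0.47) and 1.16 ± 1.03 between EpiSC and EpiLC (adjusted p = 0.496). Between the haploid p53-KO and the wild-type EpiSC libraries it was -0.996 ± 1.29 (adjusted p = 0.976). None of these passed the test, and the 2 wild-type EpiSC libraries held the highest and the lowest level among the EpiSC libraries.

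**Figure D1:**
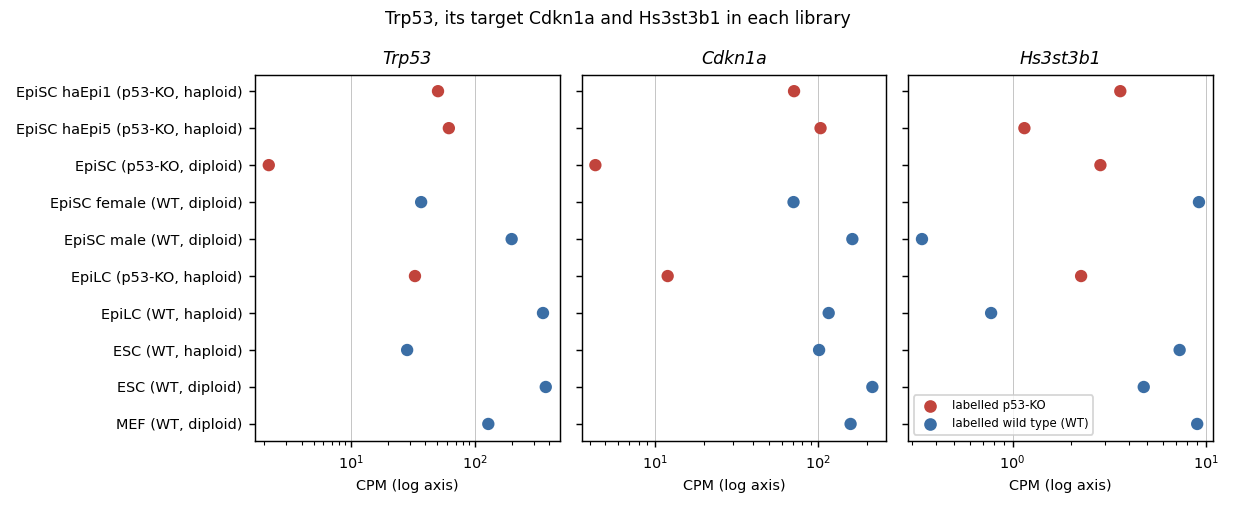
Levels of Trp53, Cdkn1a and Hs3st3b1 (TMM-normalised CPM, log axis) in the 10 libraries, 1 point each, red for libraries labelled p53-KO and blue for libraries labelled wild type. Trp53 was lowest in the diploid p53-KO EpiSC library (2.17 CPM), and haEpi1 and haEpi5 lay at 50.5 and 61.8 CPM.

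The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and the X-inactivation transcript Xist report the sex chromosomes a library carries. Ddx3y stood at 94.2 CPM in the male EpiSC library, 117 CPM in the diploid p53-KO EpiSC library, 69.4 CPM in MEF and 46.1 CPM in the wild-type haploid EpiLC library. It stood at 8.49 CPM in haEpi1, 5.01 CPM in haEpi5, 5.75 CPM in female EpiSC, 2.30 CPM in haploid ESC, 0.630 CPM in p53-KO EpiLC and 0 in diploid ESC. Eif2s3y ran from 0 in diploid ESC to 96.7 CPM in diploid p53-KO EpiSC, with 47.8 CPM in the wild-type haploid EpiLC library. Uty stood at 26.5 CPM and Kdm5d at 0.774 CPM in that library, against 39.3 and 48.1 CPM in male EpiSC. Xist was highest in MEF (754 CPM), followed by haEpi5 (168 CPM), haploid ESC (82.3 CPM), female EpiSC (46.2 CPM) and haEpi1 (39.1 CPM). The strand of the reads is not stated, so Xist and its antisense gene Tsix cannot be told apart.

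EpiSC were compared with ESC (5 against 2 libraries) to show what separates the post-implantation from the pre-implantation state. Of 20 measured genes of naive pluripotency, the ground state of the early epiblast, 16 fell in EpiSC, with a median log2 fold change of -6.04. Prdm14, a regulator of that state, fell by 9.60 on the log2 scale (SE 1.24, edgeR adjusted p = 0.0013), and Dppa5a lay at 0.808 CPM in EpiSC against 726 CPM in ESC (-9.80 ± 0.62, adjusted p = 5.22e-05). Of 19 genes of the post-implantation epiblast, 14 rose and none fell, with a median of 2.78. Fgf5, the marker growth factor of that epiblast, reached 47.0 ± 16.1 CPM (SD, n = 5) against 0.106 ± 0.059 CPM (n = 2), a log2 fold change of 8.65 ± 0.79 (adjusted p = 0.000238), and the transcription factor gene Sox11 rose by 4.86 ± 0.72 (adjusted p = 0.00246). Germline genes stood high in ESC: 17 of 18 fell in EpiSC, among them Dazl, an RNA-binding factor of germ cells, from 156 ± 168 CPM to 0.0516 ± 0.0721 CPM (-11.29 ± 0.90, adjusted p = 0.000119).

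Of 15 genes marking the rare 2-cell-like cells of ESC cultures, 14 fell, with a median of -8.79, or -5.93 with genes at 0 in all EpiSC libraries set to their bounds. These are families of near-identical copies such as Zscan4, among which counting can divide reads, so the values of single members are uncertain. Of 17 targets of FGF-ERK signalling 6 rose, among them Dusp6, a phosphatase that restrains ERK (3.07 ± 0.34, adjusted p = 0.000637). Of 19 genes of the epithelial-mesenchymal transition 6 rose, with the splicing regulator Esrp1 (4.28) and the tight junction gene Ocln (2.69) among them. This list holds epithelial genes, such as Esrp1 and Ocln, beside mesenchymal ones, such as Vim and Twist1. Here and in the later comparisons, a shift of this list therefore gives no direction of the transition. Of 15 general pluripotency genes 2 rose and 4 fell: Epcam, an epithelial adhesion gene, rose by 2.08 ± 0.43 (adjusted p = 0.011), and Dnmt3l, a cofactor of DNA methylation, fell by 8.67 on the log2 scale. Of 12 genes of the DNA methylation machinery 4 fell, among them Zfp57, which guards imprints (-2.44). Of 11 Nodal pathway genes 3 rose and 2 fell, with Smad7, an inhibitor of TGF-beta family signalling, at -1.52. Of 26 paternally expressed imprinted genes 4 rose, with Nnat at 3.68, and of 19 maternally expressed ones 3 rose and 2 fell, with Slc22a3 at 7.07 and Cobl at -4.53. Of 21 heparan sulfate enzymes 5 rose and none fell; Ndst3, an N-deacetylase, was at 0 in both ESC libraries and at least 2.58 higher in EpiSC on the log2 scale. Among 18 genes of the primitive streak 3 fell, with Cdx1 at -5.74, and among 18 of the extraembryonic endoderm 1 rose and 3 fell, with Lama1 at -3.92. Of 30 p53 targets 2 rose, with the apoptosis gene Pmaip1 at 1.96, and 2 fell, with Tigar at -1.56. In the trophoblast list 1 of 17 genes fell, in the Wnt target list 1 of 16 rose and 1 fell, in the glycolysis list 1 of 21 rose and 2 fell, and in the mitotic list 0 of 22 passed the edgeR test.

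By camera with a preset correlation, 10 of the lists differed: naive pluripotency (adjusted p = 3.41e-13), post-implantation epiblast (2.01e-12), germline (3.4e-15), 2-cell-like (5.86e-12), FGF-ERK targets (0.000387), epithelial-mesenchymal transition (0.000112), neural (0.00975), fibroblast (7.21e-05), paternally expressed imprinted (0.0076) and respiratory chain genes (0.0272). With an estimated correlation none of them did: the adjusted p = 0.228 with an estimated correlation for naive, post-implantation and germline genes, 0.373 for 2-cell-like and epithelial-mesenchymal genes, 0.428 for FGF-ERK targets and 0.545 for the other 4. Adjusted over the list alone, 18 naive genes, 18 germline genes and all 15 of the 2-cell-like genes fell, and 16 post-implantation genes rose. The fibroblast genes had a positive log2 fold change in 23 of 23 (median 1.34, 1 passing the test). The fibroblast median level was 16.6 to 63.8 CPM in 4 of the EpiSC libraries and 9.55 CPM in the diploid p53-KO EpiSC library. It was 25.1 CPM in haploid ESC and at most the floor of 0.186 CPM in diploid ESC. Here and in the later comparisons, fibroblast RNA in a culture was not told apart from expression in the pluripotent cells. Without the diploid ESC library the calls of 4 lists ended: neural (adjusted p = 0.0813), fibroblast (0.509, median 0.37, against 6.58 without the haploid ESC library), paternally expressed imprinted (0.0512) and respiratory chain genes (0.421). For the extraembryonic endoderm list the median was 0.08, the mean negative and the camera direction up (adjusted p = 0.903). For trophoblast the median was 0.19 and the camera direction down (adjusted p = 0.982).

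Over all genes, 3573 of 21104 changed between EpiSC and ESC by edgeR, 1447 up and 2126 down in EpiSC; 3317 of them changed at least 2-fold and 3363 also passed in DESeq2, which called 4375. Among the genes with the largest increases were Car4, a carbonic anhydrase (167 ± 118 against 0.391 ± 0.281 CPM), Calcr, the calcitonin receptor gene (8.34 ± 0.51, adjusted p = 5.14e-05), and Fndc3c1 (8.18 ± 0.88). Among the largest decreases were the helicase gene D1Pas1, at 0 in all EpiSC libraries and 45.1 ± 4.72 CPM in ESC (a fold bound of -8.07 on the log2 scale, floor 3 counts per library), Crxos (a bound of -7.85) and Khdc3 (a bound of -7.22). The count fell to 1626 without the diploid ESC library, to 1553 without haEpi1 and haEpi5, to 2243 with covariates for p53 label and ploidy and to 70 with wild-type libraries only. Of 80 gene calls named by the rule 48 remained without the diploid ESC library and 64 without the haploid ESC library.

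**Figure D2:**
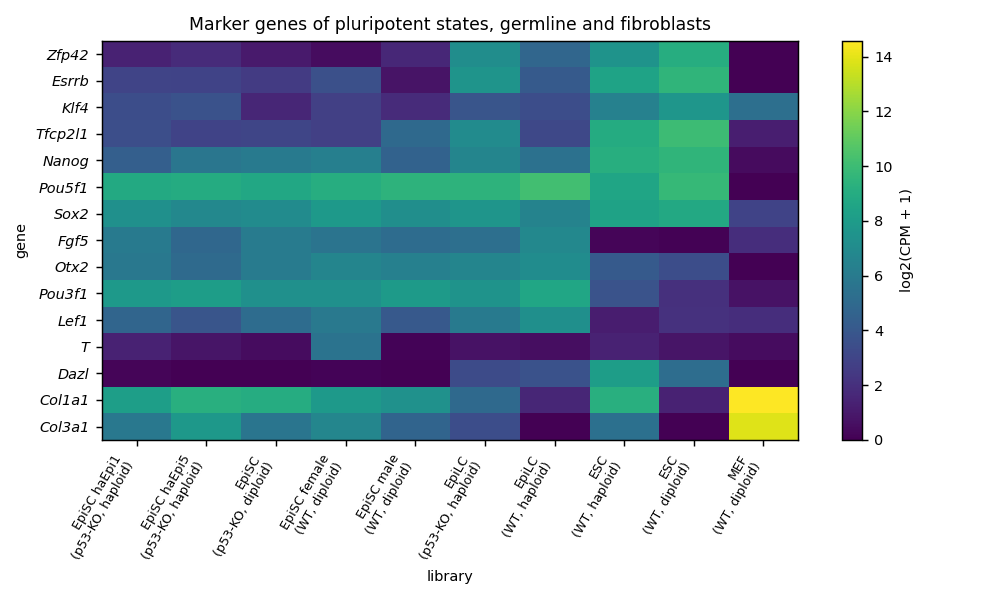
Heat map of log2(CPM + 1) of markers of naive pluripotency, post-implantation epiblast, general pluripotency, primitive streak, germline and fibroblasts in the 10 libraries. Dazl stood at 156 ± 168 CPM in the ESC libraries and 0.0516 ± 0.0721 CPM in the EpiSC libraries, and Fgf5 at 0.106 ± 0.059 and 47.0 ± 16.1 CPM.

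EpiLC were compared with ESC (2 against 2 libraries) to show the first step out of the naive state. The share of ribosomal RNA genes was 0.0455% in the p53-KO and 0.0231% in the wild-type EpiLC library. In haploid and diploid ESC it was 0.00208% and 0.00437%, so this share differed between the sides of the contrast. It did not follow cell type alone. Among EpiSC it was 0.0152% in the diploid p53-KO library and 0.000962 to 0.0013% in the others. Whatever sets this share was not told apart from the cell type here. Of 19 genes of the post-implantation epiblast 5 rose (16 adjusted over the list alone), with 19 of 19 positive and a median log2 fold change of 2.92. Fgf5 reached 75.9 ± 51.9 CPM against 0.106 ± 0.059 CPM (9.33 ± 0.83, edgeR adjusted p = 0.00384), Pou3f1, a neural and epiblast transcription factor gene, rose by 5.24 ± 0.67 (adjusted p = 0.0249) and Lef1, a Wnt effector, by 5.63 ± 0.88 (adjusted p = 0.0345). Of the FGF-ERK targets 2 rose (6 adjusted over the list alone): Dusp6 by 4.11 ± 0.38 (adjusted p = 0.00407) and Spry1, a receptor tyrosine kinase inhibitor, by 1.98 ± 0.29. Of 20 naive genes 17 had a negative value with a median of -2.27, none passed the edgeR test over all genes and 3 passed adjusted over the list alone; Klf4 stood at -3.62 ± 0.85 (adjusted p = 0.114) and Nanog at -3.23 ± 0.68 (adjusted p = 0.0833).

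Camera gave adjusted p = 2.23e-17 for the post-implantation list, 2.36e-06 for naive genes, 2.36e-06 for FGF-ERK targets, 6.23e-06 for 2-cell-like genes (15 of 15 negative, median -2.88), 0.0114 for general pluripotency genes (median 0.74) and 0.0462 for extraembryonic endoderm genes (median -1.19). With an estimated correlation none remained: adjusted p = 0.198 with an estimated correlation for the post-implantation list, 0.447 for naive, general pluripotency and FGF-ERK genes, 0.765 for 2-cell-like genes and 0.821 for extraembryonic endoderm genes. Without the haploid ESC library the calls of the 2-cell-like list (adjusted p = 0.165, median -0.70) and of the general pluripotency list (0.291) ended. The extraembryonic endoderm call ended without the haploid ESC (adjusted p = 0.705, median 0.15), the wild-type haploid EpiLC or the male EpiSC library. The naive median was -1.34 without the diploid ESC, -1.45 without the wild-type haploid EpiLC and -3.92 without the p53-KO EpiLC library, and the post-implantation median was 2.92 with all libraries and 1.73 without the wild-type haploid EpiLC library. Fibroblast genes had a median of -2.34, or -2.03 with bounds (adjusted p = 0.325), which turned to 2.72 without the haploid ESC library.

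In all, 90 of 21104 genes changed between EpiLC and ESC by edgeR, 67 up and 23 down, while 3035 had an unadjusted p under 0.05 (1055 expected by chance) and DESeq2 called 960, which included the 90. By limma on log2(FPKM + 1) the balance turned, with 105 up and 205 down. Among them Car4 rose by 7.72 ± 1.22, Bcl11a, a zinc finger transcription factor gene, by 6.72 ± 0.94 and Vrtn by 5.84 ± 0.89. Prss35 fell from 15.8 ± 1.56 to 0.416 ± 0.124 CPM (-5.22 ± 0.51, adjusted p = 0.00537) and Epha4, an ephrin receptor gene, fell by 3.91 on the log2 scale. Single libraries moved this count: 1 gene passed without the diploid ESC library, where Fgf5 and Dusp6 both had adjusted p = 0.0514, and 6 passed without the wild-type haploid EpiLC library, while 216 passed without the p53-KO EpiLC library. With wild-type libraries only 0 passed, with covariates for p53 label and ploidy 29 and with no low-count filter 676. Of 22 gene calls named by the rule, 0 remained without the diploid ESC library, 2 without the wild-type haploid EpiLC library, 11 without the haploid ESC library and 18 without the p53-KO EpiLC library.

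EpiSC were compared with EpiLC (5 against 2 libraries), the stable and the transient form of the epiblast state. Of 18 germline genes 16 fell in EpiSC, with a median log2 fold change of -7.27. Mael, a gene of the piRNA pathway, stood at 48.7 ± 31.5 CPM in EpiLC (SD, n = 2), with 1 count over the 5 EpiSC libraries (edgeR adjusted p = 0.000155), and Stk31, a germ cell kinase gene, at 20.4 ± 15.0 CPM, with 3 counts (adjusted p = 0.000158). Of 20 naive genes 10 fell, with Dppa3, a maternal factor that protects methylation, at -6.86 ± 0.91 and Dppa5a at -9.83 ± 0.62 (adjusted p = 5.73e-05). Of 15 general pluripotency genes 5 fell, with Dppa4 at -7.84 and Dnmt3l at -9.41 ± 0.62, and of 15 2-cell-like genes 10 fell. Fibroblast genes were positive in 23 of 23 with a median of 3.53 (5.57 without the p53-KO EpiLC library); 2 of them rose, with Pdgfrb, the PDGF receptor beta gene, at 2.57 ± 0.41 (adjusted p = 0.00638), and 8 adjusted over the list alone. The fibroblast median level was 5.41 CPM in the p53-KO EpiLC library and 0.71 CPM in the wild-type haploid EpiLC library, against 9.55 to 63.8 CPM in the EpiSC libraries. Beside these, 4 genes of the epithelial-mesenchymal transition rose (8 adjusted over the list alone) and 4 of 21 heparan sulfate enzymes rose (7 adjusted over the list alone); Ext1, which builds the heparan sulfate chain, rose by 1.08 ± 0.20 (adjusted p = 0.0117), but had adjusted p = 0.0857 without the p53-KO EpiLC library.

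Camera gave adjusted p = 1.01e-16 for germline, 1.06e-07 for naive, 4.35e-08 for 2-cell-like, 1.06e-07 for fibroblast, 5.65e-05 for general pluripotency and for epithelial-mesenchymal, 0.00487 for heparan sulfate, 0.00158 for respiratory chain, 0.00119 for neural, 0.000913 for mitotic and 0.0134 for DNA methylation genes. With an estimated correlation none of the 11 remained: the adjusted p = 0.285 with an estimated correlation for germline and general pluripotency genes, 0.356 for naive, heparan sulfate and epithelial-mesenchymal genes, 0.398 for DNA methylation genes, 0.408 for 2-cell-like, fibroblast, neural and respiratory chain genes and 0.588 for mitotic genes. The neural call ended without the p53-KO EpiLC library (adjusted p = 0.0619), and the mitotic (0.128) and DNA methylation (0.186) calls ended without the wild-type haploid EpiLC library. The medians were -6.26 for 2-cell-like genes (-2.94 with bounds), 2.28 for neural genes (1.41 with bounds) and -0.45 for mitotic genes, 4 of which fell. The post-implantation list had a median of -0.32 and a camera direction up (adjusted p = 0.808), and the p53 target list a median of -0.01 and a positive mean (adjusted p = 0.87).

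In total 2036 of 21104 genes changed between EpiSC and EpiLC, 796 up and 1240 down; DESeq2 called 3616, of which 2004 were shared. Eya4, a transcriptional coactivator gene, rose from 0.224 ± 0.039 to 11 ± 4.84 CPM, Fibin was at 0 in both EpiLC libraries and at least 5.10 higher in EpiSC on the log2 scale, and D1Pas1 was at 0 in all EpiSC libraries, with a bound of -7.16. The count was 554 without the p53-KO EpiLC library, 1002 without the wild-type haploid EpiLC library, 1226 without haEpi1, 1357 without haEpi5, 1313 without the female EpiSC library, 418 without haEpi1 and haEpi5, 1279 with covariates for p53 label and ploidy, 3162 with no low-count filter and 0 with wild-type libraries only. Of 68 gene calls named by the rule 22 remained without the p53-KO EpiLC library and 29 without the wild-type haploid EpiLC library.

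EpiSC were compared with MEF (5 against 1 library), the cell type farthest from pluripotency among the samples. Of 15 general pluripotency genes 10 rose in EpiSC and none fell, with a median log2 fold change of 7.50 (7.30 with bounds). Pou5f1, the gene of the core pluripotency factor OCT4, stood at 520 ± 93.6 CPM in EpiSC (SD, n = 5) and 0 in MEF, at least 11.40 higher on the log2 scale, and Lin28a, which represses let-7 microRNAs, at 319 ± 105 CPM and at least 10.69 higher. Of 19 post-implantation genes 11 rose and 1 fell, with the homeobox gene Otx2 among those that rose. Nodal pathway genes rose in 6 of 11, with a median of 3.71. Fibroblast genes fell in 16 of 23, with a median of -4.28; the collagen genes Col3a1 and Col6a3 stood at -7.36 ± 1.68 and -8.29 ± 1.16. Of the heparan sulfate enzymes 8 fell and none rose, with Hs3st1, another 3-O-sulfotransferase, at -3.44 and Ndst1 at -1.73; adjusted over the list alone 2 rose and 13 fell. Mitotic genes rose in 6 of 22 (12 adjusted over the list alone), with the spindle checkpoint kinase gene Bub1 at 2.12. Extraembryonic endoderm genes fell in 9 of 18, with Pdgfra at -5.79. Among the largest decreases was Aspn, which encodes a small matrix proteoglycan, from 279 CPM in MEF to 0.209 ± 0.149 CPM in EpiSC (-10.32 ± 0.61, edgeR adjusted p = 7.89e-05).

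The general pluripotency call had adjusted p = 2.38e-16 by camera and adjusted p = 0.0221 with an estimated correlation, the only call among the 91 of all comparisons that passed with that setting. The other 10 calls in EpiSC against MEF were post-implantation (1.01e-08), fibroblast (1.11e-08), mitotic (2.42e-07), Nodal pathway (3.21e-06), heparan sulfate (0.000492), extraembryonic endoderm (0.000802), glycolysis (0.00135, median 1.13), trophoblast (0.00855, median 3.10 and 2.95 with bounds), naive (0.02, median 3.11 and 1.67 with bounds) and FGF-ERK genes (0.0236). With an estimated correlation the adjusted p = 0.0632 for Nodal pathway, 0.218 for post-implantation and heparan sulfate, 0.464 for fibroblast, mitotic and extraembryonic endoderm and 0.601 for glycolysis, trophoblast, naive and FGF-ERK genes. The epithelial-mesenchymal list had a median of -0.62 with a positive mean (1.54, adjusted p = 0.381). The germline list had a median of 0.96, or -1.80 with bounds, and a camera direction down (adjusted p = 0.8). The neural list had a median of 0.34, or -0.27 with bounds (adjusted p = 0.915), and the maternally expressed imprinted list a median of -0.49 and a mean of 0.25 (adjusted p = 0.701). Over all genes 3106 of 21104 changed, 1252 up and 1854 down, and 4082 changed by DESeq2, of which 2886 were shared. The MEF group held 1 library, whose spread was assumed to be that of the other groups, and 1781 genes changed without haEpi1 and haEpi5.

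The haploid p53-KO and the wild-type EpiSC libraries were compared (2 against 2) to ask whether the haploid lines differ from diploid cells of the same type; in this contrast p53 label and ploidy change together. Fibroblast genes had a positive value in 22 of 23, with a median log2 fold change of 1.12; Col1a1, a collagen chain gene, stood at 1.15 ± 0.39 and Mmp2, a matrix metalloproteinase gene, at 0.96 ± 0.27. Lefty2 and Lefty1, inhibitors of Nodal signalling, stood at 3.78 ± 0.54 and 1.75 ± 0.39, and Dnmt3b, a de novo DNA methyltransferase gene, at -1.09 ± 0.29. Trp53 stood at -1.06 ± 0.68 and Cdkn1a at -0.41 ± 0.42 (edgeR adjusted p = 0.976 for both). None of these genes passed the test: edgeR called 0 of 18153 genes (641 with an unadjusted p under 0.05, 907.6 expected by chance), DESeq2 22 and limma on log2(FPKM + 1) 0. By camera 10 lists differed, and with an estimated correlation none did. The fibroblast call (adjusted p = 1.05e-12, or adjusted p = 0.526 with an estimated correlation) was the only one of the 10 that was kept when each library was left out, with a median of 0.63 without haEpi5 and 1.97 without the female library. Among the others were Nodal pathway genes (median 0.34, adjusted p = 0.00211, lost without haEpi1 at 0.127; median 0.53 without haEpi5, 0.68 without the female and 0.92 without the male library), mitotic genes (-0.23, 0.00136, lost without the male library at 0.271 and a median of -0.15; -0.41 without the female library), trophoblast genes (0.67, 0.000486, lost without haEpi1 at 0.121 and a median of 0.32; 1.12 without the male library) and post-implantation genes (-0.47, 0.00452, lost without haEpi5 and without the female library, highest 0.637, median -0.058 without the female library). With an estimated correlation these 4 had adjusted p = 0.526 or, for mitotic genes, adjusted p = 0.578. The p53 target list had a median of -0.25 (adjusted p = 0.266), which turned to 0.39 without the male library. Without the female EpiSC library edgeR called 144 genes, and without the male EpiSC library 9.

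Between haploid and diploid p53-KO EpiSC (2 against 1 library), the contrast of ploidy at 1 p53 label, Trp53 stood at 4.71 ± 1.12 (edgeR adjusted p = 0.634) and Cdkn1a at 4.35 ± 0.67 (adjusted p = 0.381). Of 30 p53 targets 23 were positive, with a median of 0.86 and 2 passing adjusted over the list alone; Ak1, an adenylate kinase gene, stood at 2.71 ± 0.42. Fibroblast genes were positive in 19 of 23 with a median of 2.12, and Prrx1 and Thy1, genes of mesenchymal cells, stood at 4.36 ± 0.95 and 3.37 ± 0.77. Mitotic genes were negative in 21 of 22, with a median of -0.47. The imprinted growth factor gene Igf2 stood at -3.56 ± 0.56. None of these genes passed the test over all genes: edgeR called 0 of 18153 (1007 with an unadjusted p under 0.05, 907.6 expected by chance, smallest adjusted p = 0.0841), DESeq2 268 and limma 0. Camera called 8 lists. It gave adjusted p = 5.43e-08 for fibroblast genes, 3.3e-07 for p53 targets, 3.3e-07 for mitotic genes and 4.07e-05 for glycolysis genes (median -0.45, lost without haEpi5 at 0.558 and a median of 0.038). For each of these 4 lists the adjusted p = 0.669 with an estimated correlation. The other 4 were paternally expressed imprinted (0.0079), trophoblast (0.0294), FGF-ERK (0.0294) and post-implantation genes (0.0365), with adjusted p = 0.677 with an estimated correlation for the imprinted and FGF-ERK genes and 0.669 for the other two. The trophoblast and FGF-ERK calls ended without haEpi1 (0.343 and 0.249) and the post-implantation call without haEpi5 (0.336). The diploid group held 1 library, so its spread was taken from the other groups. The sides also differed in sex chromosomes. The summed level of the Y-linked genes was 312 CPM in the diploid library, 18.6 CPM in haEpi1 and 16.6 CPM in haEpi5. The X balance of haEpi5 (-0.171) lay among the libraries labelled diploid. The differences of this contrast therefore cannot be laid to ploidy alone.

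Between diploid p53-KO and wild-type EpiSC (1 against 2 libraries), the contrast of the p53 label at 1 ploidy, Trp53 stood at -5.77 ± 1.17 (edgeR adjusted p = 0.835) and Cdkn1a at -4.75 ± 0.68 (adjusted p = 0.463). Of 30 p53 targets 26 were negative, with a median of -1.07 and 2 passing adjusted over the list alone; Ak1 stood at -2.21 ± 0.40. Camera gave adjusted p = 3.09e-11 for the list, or adjusted p = 0.956 with an estimated correlation, and the call was kept without either wild-type library, with a median of -0.61 without the male one. The share of ribosomal RNA genes also differed, at 0.0152% in the p53-KO library, 0.00129% in the female and 0.0013% in the male library. This was not told apart from the p53 label. Igf2 stood at 3.35 and the placental transcription factor gene Hand1 at 4.91. Glycolysis genes (median 0.36, adjusted p = 0.00923) and mitotic genes (0.18, adjusted p = 0.0144) differed too, both with adjusted p = 0.956 with an estimated correlation, and both calls ended without the female library (0.447 and 0.538). No gene passed: edgeR called 0 of 18153 (700 with an unadjusted p under 0.05, 907.6 expected by chance, smallest adjusted p = 0.0692), DESeq2 135 and limma 0. Without the female library edgeR called 42 genes, and without the male library 152.

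Across the 9 pluripotent libraries, 4 labelled p53-KO were compared with 5 labelled wild type, adjusted for cell type and ploidy. By the labels both ESC libraries are wild type and all haploid EpiSC are p53-KO. At the same cell type and ploidy the p53 labels thus meet only in the EpiLC pair and the diploid EpiSC libraries. The EpiLC libraries also differ in Y-linked level and X balance, for which the fit was not adjusted. Leaving out either library of the EpiLC or ESC pair takes the whole pair out of the comparison, so such fits are not separate checks. Of 30 p53 targets 26 were negative, with a median of -0.78; Cdkn1a stood at -2.97 ± 1.13 and Phlda3, a repressor of Akt signalling, at -2.95 ± 1.15. Naive genes were positive in 18 of 20 with a median of 1.14, among them the adhesion gene Pecam1 (2.43 ± 0.28, edgeR adjusted p = 0.378), and post-implantation genes were negative in 18 of 19 with a median of -0.66. None of these genes passed the test: edgeR called 0 of 18659 genes (572 with an unadjusted p under 0.05, 933 expected by chance), DESeq2 24 and limma 0. Camera gave adjusted p = 4.25e-08 for p53 targets, 2.62e-07 for naive and 3.64e-06 for post-implantation genes, and each had adjusted p = 0.814 with an estimated correlation. The p53 target call ended without the diploid p53-KO EpiSC library (0.0519, median -0.51), and the median was -0.47 without either EpiLC library and -1.22 without either ESC library. The naive call ended without the p53-KO or the wild-type EpiLC library (highest 0.107, median 0.14 without either), as did the post-implantation call (highest 0.579, median -0.28 without either). Without the diploid p53-KO EpiSC library these medians were 2.07 and -1.07, and without the female library the naive median was 1.81. The trophoblast (0.0123) and neural (0.0363) calls had adjusted p = 0.922 with an estimated correlation, and the median of trophoblast genes turned from 0.40 to -0.38 without either EpiLC library, where its call ended (highest 0.579). The neural call ended without the female EpiSC, either ESC or either EpiLC library (highest 0.498).

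Libraries labelled haploid were compared with diploid ones (5 against 4 libraries), adjusted for cell type and p53 label. At the same cell type and p53 label the ploidies meet only in the ESC pair and the p53-KO EpiSC libraries. Leaving out either ESC library takes the ESC pair out of the comparison, so these fits are not separate checks. Fibroblast genes were positive in 22 of 22 with a median of 2.60. Twist1, a mesenchymal transcription factor gene, stood at 2.90 ± 0.81 and Fbn1, which encodes fibrillin, at 2.05. Fibroblast genes stood at a median of 3.62% of their MEF level in haploid ESC and 0.00683% in diploid ESC. The Y-linked sum was 5.84 CPM and 0 there. Fibroblast RNA in the cultures was not told apart from expression in the haploid cells. Mitotic genes were negative in 21 of 22 with a median of -0.33. Camera also called epithelial-mesenchymal (median 0.66), extraembryonic endoderm (1.02), trophoblast (0.91) and naive genes (-0.72). Each of these calls ended without either ESC library. FGF-ERK targets had a median of 0.72, Lefty2 stood at 2.47 ± 0.40 (edgeR adjusted p = 0.695) and the germ cell gene Taf7l at 5.00 ± 0.68 (adjusted p = 0.411). None of these genes passed the test: edgeR called 0 of 18659 (881 with an unadjusted p under 0.05, 933 expected by chance), DESeq2 41 and limma 0. Of 14 list calls, those of fibroblast genes (adjusted p = 2.93e-14) and FGF-ERK targets (0.000449) were kept when each library was left out, although both had adjusted p = 0.463 with an estimated correlation, and the fibroblast median was 1.29 without the haploid and 1.28 without the diploid ESC library. The mitotic call (1.35e-05, or adjusted p = 0.463 with an estimated correlation) ended without the diploid p53-KO EpiSC library (0.108). The calls of 2-cell-like genes (median 2.42, adjusted p = 0.002) and germline genes (1.38, adjusted p = 0.00447), with adjusted p = 0.517 with an estimated correlation for both, ended without the haploid and without the diploid ESC library, where the medians turned to -0.61 and -0.59 for the first list and to -0.23 and -0.26 for the second.

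A haploid cell carries 1 X chromosome for 1 set of autosomes, and a diploid cell with 1 active X carries 1 for 2 sets. Relative to the autosomal genes, the X-linked genes stood at 0.43 on the log2 scale in haEpi1 (95% bootstrap interval 0.37 to 0.48), 0.44 in haploid ESC (0.37 to 0.51) and 0.50 in p53-KO haploid EpiLC (0.46 to 0.57), over 356 X-linked and 9462 autosomal genes. The other 2 libraries labelled haploid lay at -0.17 in haEpi5 (-0.24 to -0.11) and -0.23 in wild-type haploid EpiLC (-0.30 to -0.16). The libraries labelled diploid lay at -0.080 in female EpiSC, -0.25 in male EpiSC, -0.11 in p53-KO EpiSC and -0.40 in ESC. The mean was 0.19 ± 0.36 for the haploid label (SD, n = 5) and -0.21 ± 0.15 for the diploid label (n = 4; exact two-sided permutation test over 126 splits, p = 0.111). In the adjusted comparison the median log2 fold change of 722 X-linked genes was 0.42, with 81.3% positive, against 0.0040 for autosomal genes (camera p = 1.75e-08, or p = 0.332 with an estimated correlation). The median was 0.023 without the haploid ESC library and 0.0017 without the diploid ESC library, and the camera call ended in both. The median was 0.673 without the wild-type haploid EpiLC library. The fits without an ESC library are not separate checks, since each takes the ESC pair out of the comparison.

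**Figure D3:**
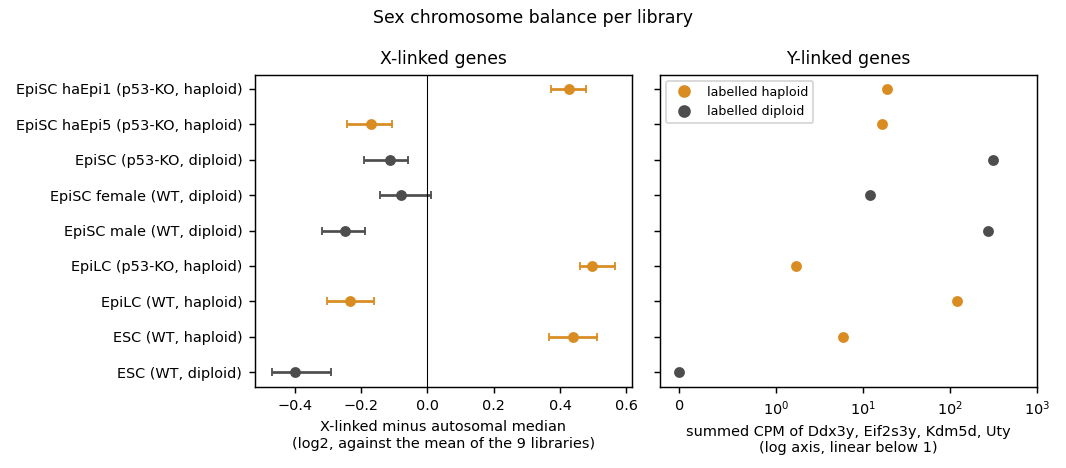
Left, median log2 level of X-linked genes minus that of autosomal genes in the 9 pluripotent libraries, with 95% bootstrap intervals from 1000 draws; right, summed CPM of Ddx3y, Eif2s3y, Kdm5d and Uty (log axis, linear below 1), orange for the haploid and grey for the diploid label. Of the 5 libraries labelled haploid, haEpi1, haploid ESC and p53-KO EpiLC lay between 0.43 and 0.50, and haEpi5 and wild-type EpiLC at -0.17 and -0.23.

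Interaction tests asked whether the p53 difference in EpiLC differed from that in diploid EpiSC. The EpiLC libraries differ in sex chromosomes along with the p53 label. The EpiLC and diploid p53-KO EpiSC groups here, and the ESC groups of the second test below, hold 1 library each, none of which could be left out; their spread was assumed to be that between the paired EpiSC libraries, so these p-values hold no replicate spread of EpiLC or ESC. For naive genes the median of the difference was 3.20 (camera adjusted p = 0.0128) and for post-implantation genes -1.02 (0.000569), with adjusted p = 0.673 with an estimated correlation for both; without the female EpiSC library the medians were 0.99 and -1.61. Gapdh, a glycolytic enzyme gene, stood at -6.87 ± 0.78 (edgeR adjusted p = 0.0752). No gene passed: edgeR called 0 of 20583 (1578 with an unadjusted p under 0.05, 1029 expected by chance, smallest adjusted p = 0.0721), DESeq2 334 and limma 164. Without the female EpiSC library edgeR called 286 genes, and without the male library 309. A second test asked whether the ploidy difference in ESC differed from that in p53-KO EpiSC. In p53-KO EpiSC the level of Y-linked genes differs along with the ploidy label. For fibroblast genes the median was 3.49 (adjusted p = 5.6e-05, 12 adjusted over the list alone) and for p53 targets -1.79 (2.24e-06, 12 adjusted over the list alone), with adjusted p = 0.708 with an estimated correlation for both. Col1a1 stood at 8.73 ± 0.83 (adjusted p = 0.0802) and Cdkn1a at -5.41 ± 0.86 (adjusted p = 0.199). No gene passed there either: edgeR called 0 of 20583 (1434 with an unadjusted p under 0.05, 1029 expected by chance), DESeq2 244 and limma 671.

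The EpiLC library labelled haploid p53-KO was set beside the one labelled haploid wild type; with 1 library each, the difference has no replicate check and no test was made. Naive genes were higher in the p53-KO library in 17 of 20, with a median log2 ratio of 2.74, and post-implantation genes lower in 17 of 19, with a median of -1.22. Their medians lay at percentiles 100 and 0 among 10000 random lists of matched expression. Trophoblast genes were higher in 15 of 15 (median 2.01, percentile 100), fibroblast genes in 18 of 22 (1.48, percentile 100), and p53 targets were lower in 25 of 29 (-1.26, percentile 0). Heparan sulfate enzymes had a median of -0.04 (percentile 27.85). At least a 2-fold difference was seen in 1812 of 10406 genes, 1120 higher and 692 lower. Usp18, an interferon-induced protease gene, had 804 counts against 0, at least 8.02 higher on the log2 scale, and Xaf1, another interferon-induced gene, stood at 8.11. Among the largest decreases were the Y-linked genes Uty (-6.72), Eif2s3y (-5.99) and Ddx3y (-5.945, 10 counts against 715). The X-linked genes were higher in the p53-KO library by a median of 0.70, with 84.3% higher, and the genes of chromosomes 8 and 6 were lower, at -0.38 and -0.26.

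The haploid ESC library was set beside the diploid ESC library in the same way, without a test. Fibroblast genes were higher in haploid ESC in 22 of 22, with a median log2 ratio of 5.59 (percentile 100). So were 2-cell-like genes in 15 of 15 (2.89, percentile 100) and germline genes with a median of 2.43 (percentile 100). Trophoblast genes were higher in 16 of 16 (1.98, percentile 100). The medians of extraembryonic endoderm (1.9), epithelial-mesenchymal (1.8) and neural genes (1.3) lay at percentiles 100, 100 and 99.72. Naive genes were lower in 18 of 20 (-1.05, percentile 0), general pluripotency genes in 14 of 15 (-0.68, percentile 0.23) and p53 targets in 25 of 30 (-1.13, percentile 0). Heparan sulfate enzymes had a median of 0.36 (percentile 95.98). At least a 2-fold difference was seen in 2306 of 10870 genes, 1452 higher and 854 lower. Tnc, which encodes tenascin-C, and Lox, the lysyl oxidase gene, had 0 counts in diploid ESC and were at least 10.86 and 10.16 higher on the log2 scale, and Thbs1, a thrombospondin gene, had 15292 counts against 7. The X-linked genes were higher by a median of 0.81, with 90.2% of them higher.

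Chromosome medians described whole-chromosome shifts within the EpiSC libraries. In the female EpiSC library the 346 genes of chromosome 12 stood 0.69 above the mean of the other EpiSC libraries on the log2 scale, with 96.2% of them higher, while the other autosomes lay between -0.11 and -0.016. Against the mean of all 5 libraries the chromosome 12 median was 0.55. The X chromosome median of haEpi1 was 0.40, and that of the other EpiSC libraries -0.18 to -0.030.

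**Figure D4:**
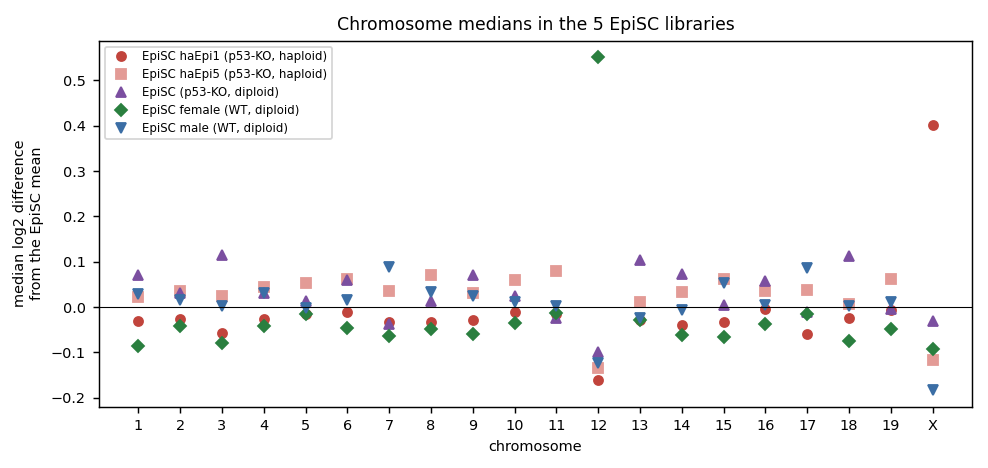
Median log2 difference of the genes of each chromosome from the mean of the 5 EpiSC libraries, per EpiSC library. Chromosome 12 of the female library lay at 0.55 and the X chromosome of haEpi1 at 0.40.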

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

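Apart from the matched gene sets of chromosome 12 and the splits of the samples, the tests of explanations below were chosen only after the result was seen.

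In the 5 EpiSC libraries 57 measures were screened for a library far from the other 4, and 8 were found. Chance would give about 2.85 for independent measures of alike libraries. These libraries differ by label and the measures overlap, as for the X chromosome of haEpi1. The 8 therefore do not show an excess over chance. The share of mitochondrial counts was 3.83% in haEpi5 (exact 95% interval 3.82 to 3.84) and 1.30 to 2.02% in the other EpiSC libraries. The share of ribosomal RNA genes was 0.0152% in the diploid p53-KO EpiSC library (exact 95% interval 0.0146 to 0.0158) against 0.000962 to 0.0013% in the others. Xist stood at 168 CPM in haEpi5 against 2.42 to 46.2 CPM. The median of chromosome 11 was 0.079 above the EpiSC mean in haEpi5 on the log2 scale, against -0.023 to 0.0013, that of chromosome 12 was 0.55 in the female library, against -0.16 to -0.099, and that of the X chromosome was 0.40 in haEpi1, against -0.18 to -0.030. The X-linked genes stood 0.43 above the autosomal genes in haEpi1, against -0.25 to -0.080. The mean level of respiratory chain genes was 6.73 log2 CPM in the diploid p53-KO library, against 6.94 to 7.01.

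Differences between effects were tested by interaction for the lists, and 13 passed with a preset correlation and none with an estimated one. The EpiLC, ESC and diploid p53-KO EpiSC groups in them hold 1 library each, with a spread assumed from the paired EpiSC libraries, so a difference between the groups is not told apart from one between single libraries. The p53 difference in EpiLC minus that in diploid EpiSC had a median log2 value of 3.20 for naive genes (camera adjusted p = 0.0128, or adjusted p = 0.673 with an estimated correlation; median 0.99 without the female EpiSC library), -1.02 for post-implantation genes (0.000569 and 0.673; -1.61 without the female library), 2.91 for trophoblast genes (0.0153 and 0.774, ended without the male EpiSC library), 2.44 for fibroblast genes (0.0143 and 0.88), 2.32 for germline genes (0.0304 and 0.673, ended without the female EpiSC library, median 1.41), 1.43 for 2-cell-like genes (0.0131 and 0.673), -0.80 for glycolysis genes (0.0153 and 0.88, ended without the female EpiSC library) and -0.66 for mitotic genes (2.2e-05 and 0.743). With genes at 0 on a side set to their bounds, the trophoblast median was 2.41 and the fibroblast median 2.06. The ploidy difference in ESC minus that in p53-KO EpiSC had a median of 3.49 for fibroblast genes (5.6e-05 and 0.708), -1.79 for p53 targets (2.24e-06 and 0.708), 1.70 for germline genes (6.91e-05 and 0.462; 2.98 without haEpi1), 2.67 for 2-cell-like genes (7.18e-15 and 0.284) and -0.58 for respiratory chain genes (0.00114 and 0.708). These 5 calls were kept without haEpi1 and without haEpi5, but no fit could be made without either ESC library or the diploid p53-KO EpiSC library, so how far they rest on those was not tested.

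The first pattern is the median of 0.69 for the 346 genes of chromosome 12 in the library labelled wild-type female EpiSC, against the mean of the other EpiSC libraries. The lowest median of 10 windows of equal gene number along the chromosome was 0.559, which argues against a few genes carrying the value. Gene sets of the other autosomes matched on GC content, length and level reached at most -0.00781 in 1000 draws, which argues against these properties. Relative to the middle of the other autosomes (-0.0596) the median was 0.749, which differs from log2(3/2) by 0.164. No other autosome deviated from that middle by more than 0.0494. That scatter of unshifted chromosomes does not show how closely a gained chromosome follows log2(3/2). The test therefore cannot decide on 1 extra copy, and a gain of chromosome 12 stays open because no DNA was measured. Apart from copy number no biological explanation was tested, because no group of the design differs in this chromosome.

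The second pattern is that X-linked genes did not lie above autosomal genes in haEpi5 and in the library labelled wild-type haploid EpiLC, while they did in the other 3 libraries labelled haploid. RNA of MEF feeder cells would need a share of 22.3% to give the Xist level of haEpi5. The Y-linked level of the EpiLC library would need 87.6%. In these libraries the fibroblast genes stood at a median of only 8.27% and 0.0405% of their MEF level. The abundant fibroblast transcript Col1a1 stood at 2.39% and 0.00788%. The Y-linked sum of haEpi5 was 16.6 CPM against 138 CPM in MEF, a larger part of the MEF level than the fibroblast median. The feeder share thus depends on the genes used, and feeder RNA was not excluded as a source of Xist in haEpi5. For haEpi5, diploid cells with 1 silenced X chromosome may account for the balance of -0.171. That balance lay among the libraries labelled diploid, while Xist lay above every other pluripotent library. Both values were seen before this explanation was chosen, and the balance defined the pattern, so they are no separate check of it. For the EpiLC library the balance of -0.234 lay among the diploid libraries and 3 of 4 Y-linked genes lay above the other libraries labelled haploid, but Kdm5d did not, and the design text names WT-EpiLCs with no ploidy, so diploid male cells under this label cannot be told apart from other sources with 1 library. Whether such diploid cells arose by a change of ploidy within a haploid-labelled culture was untested.

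The third pattern is the level of Trp53 (50.5 and 61.8 CPM) and Cdkn1a in haEpi1 and haEpi5, labelled p53-KO. RNA of MEF feeder cells would need shares of 38.2% and 47.1% to give these Trp53 levels, whereas fibroblast genes stood at 5.14% and 8.27% of MEF, which argues against it. A transcript remaining from a disrupted gene stays open: the p53 targets lay 0.86 above the diploid p53-KO library, but with 1 such library and an adjusted p = 0.669 with an estimated correlation this did not decide. Wild-type cells under these labels stay open too: the targets differed from the wild-type EpiSC libraries by a median of -0.25, which turned to 0.39 without the male library. That reference is uneven, with Trp53 at 36.9 CPM in the female and 199 CPM in the male EpiSC library. Haploid ESC, also labelled wild type, stood at 28.5 CPM. The cause of the low Trp53 level in female EpiSC and haploid ESC was not tested. The explanations cannot be told apart, because reads over the targeted part of the gene were not analysed here.

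For the comparisons of at least 3 libraries per side, 100 of the 126 splits of the 9 pluripotent libraries were drawn, the real one included. For the p53 label, 0 genes changed by edgeR (572 with an unadjusted p under 0.05, 933 expected by chance, 24 by DESeq2), and the highest of the other splits was 3. For ploidy 0 genes changed by edgeR (881 with an unadjusted p under 0.05, 933 expected by chance, 41 by DESeq2), and the highest of the other splits was 6. Since no count lies below 0, all 100 splits give as many in both cases, and these counts say nothing about chance. The X-linked median of 0.42 was reached by 27 of the 100 splits, with 1.16 as the highest of the others. The 5 list calls for p53 were reached by 87 splits (highest other 14) and the 14 for ploidy by 11 splits (highest other 17). Chance was not excluded for the X-linked median or for the numbers of list calls.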

How the results depend on the processing

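The alternatives without haEpi1 and haEpi5, without haEpi5 and the wild-type EpiLC library, and without genes of chromosome 12 or of the X and Y chromosomes were chosen only after the result was seen. The cause was not tested for any change below, except that fewer samples were fitted where libraries were left out. The share of higher genes among those changed moved by over 10 points in some settings, but not with DESeq2 size factors in edgeR. In EpiLC against ESC (74.4%) it was 58.7% with no filter, 57.2% by DESeq2, 33.9% and 44.7% by limma with FPKM pseudocounts of 1 and 0.1, 23.7% by limma with no filter, and 100% without diploid ESC (1 gene) or wild-type EpiLC (6 genes). It moved from 40.5% to 28.5% (limma with no filter) and 28.6% (without diploid ESC) in EpiSC against ESC, from 39.1% to 51.2% (DESeq2) and 23.2% (without wild-type EpiLC) in EpiSC against EpiLC, and from 40.3% to 21.2% (limma with no filter) in EpiSC against MEF. The median of all genes lay at 0.11 between EpiSC and MEF and at 0.18 in the p53 interaction, and fold changes there are relative to that shift. Depth limits genes near the floor of 3 counts. No paired analysis was possible because the groups share no usable replicate numbers. The fits that left out the lone library of a group could not be made in 9 settings (MEF, diploid p53-KO EpiSC and the single libraries of the interaction tests).

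Of 248 called values of named genes 0 reversed in any setting and 58 passed in every setting. Of the 248, 244 were kept by DESeq2, 242 with its size factors and 245 with no filter. With wild-type libraries only 9 of 170 were kept, with covariates 128 of 170 and without haEpi1 and haEpi5 145 of 226. These genes had passed the edgeR test in the same data and were picked mainly for large changes. The lack of reversals and the high numbers kept are thus largely set by that choice. Of 91 list calls 1 was kept with an estimated correlation. In comparisons where each library could be left out, 20 of 56 list calls were kept in every such fit. In the others, where a lone library could not be left out, 26 of 35 were kept in the fits that remained.

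Counts of changed genes moved as follows. EpiSC against ESC (3573) gave 70 with wild-type libraries only, 2243 with covariates and 1553 without haEpi1 and haEpi5, and with a library left out 1626 (diploid ESC) to 3009 (haploid ESC). It gave 3464 without genes of chromosome 12 and 3406 without X- and Y-linked genes. EpiLC against ESC (90) gave 676 with no filter, 960 by DESeq2, 310 and 246 by limma with FPKM pseudocounts of 1 and 0.1, 658 by limma with no filter, 0 with wild-type libraries only, 29 with covariates, and with a library left out 1 (diploid ESC) to 216 (p53-KO EpiLC). EpiSC against EpiLC (2036) gave 3162 with no filter, 3616 by DESeq2, 1260 by limma with no filter, 0 with wild-type libraries only, 1279 with covariates, 418 without haEpi1 and haEpi5, and with a library left out 554 (p53-KO EpiLC) to 1555 (male EpiSC). EpiSC against MEF (3106) gave 1781 without haEpi1 and haEpi5.

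The contrasts with 0 genes by edgeR gave more with no filter and by DESeq2: 136 and 22 for haploid p53-KO against wild-type EpiSC, 377 and 268 for haploid against diploid p53-KO EpiSC, 242 and 135 for diploid p53-KO against wild-type EpiSC, 43 and 24 for the p53 label, 63 and 41 for ploidy, 549 and 334 for the p53 interaction, and 429 and 244 for the ploidy interaction. Unadjusted counts under 0.05 are in the report. A fit of all 10 libraries gave 1 gene in each of the 2 contrasts of the diploid p53-KO EpiSC library. By limma the interactions gave 164 and 671 with a pseudocount of 1, 330 and 505 with 0.1, and 2950 and 5205 with no filter. With a library left out the range was 0 to 144 (female EpiSC) for haploid p53-KO against wild-type EpiSC, 42 (female) to 152 (male) for diploid p53-KO against wild-type EpiSC, 0 to 1 for ploidy (1 higher without the female EpiSC library, and 1 lower without the p53-KO or the wild-type EpiLC library) and 286 (female) to 309 (male) for the p53 interaction. Where all 11 comparisons could be fitted, the 91 list calls became 90 (haEpi5) to 107 (male EpiSC). Over the 7 comparisons left without the diploid p53-KO EpiSC library there were 66, against 67 with it, and over the 10 left without the diploid ESC library 79, against 86.

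For lists called with all libraries or with a library left out, the median and the camera direction both reversed in 20 fits with a library left out. Fibroblast genes in EpiLC against ESC ran from -3.21 to 2.72 (haploid ESC). In haploid p53-KO against wild-type EpiSC the range was -1.13 to 1.61 for primitive streak, -0.63 to 0.50 for neural and -1.64 to 1.07 for Wnt genes (reversed without female EpiSC), -0.50 to 0.39 for p53 targets and -0.044 to 1.15 for paternally expressed imprinted genes (male), and -0.98 to 0.35 for glycolysis genes (haEpi5). In diploid p53-KO against wild-type EpiSC it was -0.85 to 0.42 for paternally expressed imprinted and -1.20 to 1.04 for Wnt genes (female). For the p53 label it was -0.38 to 1.04 for trophoblast genes (reversed to -0.38 without either EpiLC library) and -0.24 to 0.22 for mitotic genes (0.22 without either). For ploidy it was -0.60 to 0.15 for general pluripotency (0.15 without haploid and 0.14 without diploid ESC), -0.26 to 1.80 for germline (-0.23 and -0.26) and -0.61 to 2.92 for 2-cell-like genes (-0.61 and -0.59), and -0.61 to 0.034 for glycolysis genes (haEpi5). The median alone turned, as the call ended, for extraembryonic endoderm genes in EpiLC against ESC (-1.19 to 0.15, haploid ESC), FGF-ERK targets in haploid p53-KO against wild-type EpiSC (0.20 to -0.046, male) and glycolysis genes in haploid against diploid p53-KO EpiSC (-0.45 to 0.038, haEpi5). The X-linked median of 0.42 ran from 0.0017 (diploid ESC) to 0.67 (wild-type EpiLC) and was 0.43 with autosomal scaling.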

Other observations

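The values of this part were chosen only after the result was seen, although the fibroblast list itself was fixed before the data were examined. Isg15, a ubiquitin-like modifier induced by interferon, stood at 94.7 CPM in haEpi5, 30.6 CPM in haEpi1, 26.4 CPM in female EpiSC, 21.8 CPM in male EpiSC and 0.186 CPM in diploid p53-KO EpiSC. It stood at 44.2 CPM in p53-KO EpiLC, 0.0645 CPM in wild-type EpiLC, 2.65 CPM in haploid ESC, 0.0621 CPM in diploid ESC and 101 CPM in MEF. Ifit1, an antiviral RNA-binding gene, stood at 64.5 CPM in haEpi5, 20.8 CPM in p53-KO EpiLC, 0.248 CPM in diploid p53-KO EpiSC and 0.516 CPM in wild-type EpiLC. Between these lay haEpi1 (17.5 CPM), female EpiSC (14.6 CPM), male EpiSC (3.51 CPM), MEF (45.2 CPM) and haploid ESC (1.75 CPM), and diploid ESC was at 0. Irf7, a transcription factor gene of the interferon response, stood at 51.7 CPM in haEpi5, 53 CPM in p53-KO EpiLC, 53.2 CPM in MEF and 0.930 CPM in diploid p53-KO EpiSC. Its level was 20.75 CPM in haEpi1, 19.5 CPM in female and 9.39 CPM in male EpiSC. The lowest levels beside these were 3.495 CPM in haploid ESC, 0.581 CPM in wild-type EpiLC and 0.435 CPM in diploid ESC. These genes belong to no fixed list, and no test of them was made.

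The fibroblast genes stood at a median of 5.14% of their MEF level in haEpi1, 8.27% in haEpi5, 3.41% in female EpiSC, 1.83% in male EpiSC, 1.83% in diploid p53-KO EpiSC and 3.62% in haploid ESC. They stood at 0.629% in p53-KO EpiLC, 0.0405% in wild-type EpiLC and 0.00683% in diploid ESC. Col1a1 stood at 2.42% of its MEF level in haploid ESC, 2.39% in haEpi5, 2.13% in diploid p53-KO EpiSC and 1.16% in haEpi1. The share of ribosomal RNA genes was 0.0455% in p53-KO EpiLC (exact 95% interval 0.0445 to 0.0466) and 0.0231% in wild-type EpiLC (0.0224 to 0.0238), the highest of the 10 libraries.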
